A study of Ignicoccus hospitalis KIN4/I with 16 samples.

How the data were processed

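Total RNA of the archaeon Ignicoccus hospitalis was measured on 16 single-colour NimbleGen arrays labelled with Cy3. The cells grew at 90 °C in a 300 litre fermenter on elemental sulfur, hydrogen and carbon dioxide, either alone or together with Nanoarchaeum equitans, a small archaeon that lives attached to this host. Both cultures were sampled at 4 phases of growth, mid log, late log, early stationary and late stationary, over a course of about 24 h. Each of the 8 combinations of culture and phase had 2 arrays, numbered replicate 1 and replicate 2. Per the labels, RNA was purified repeatedly from each sample, and they do not say that the replicate arrays came from separate cultures. All p-values here therefore measure a difference against the spread between these arrays, which need not be the spread between independent cultures.

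The scanner files deposited by the authors give for each feature the average intensity over its probe spots, with no further step stated. They also give a ratio, the coefficient of variation of the spots, per the file headers, which was used only to describe the arrays. Mismatch columns were 0 throughout and were not used. Single probe values were not used here, so the median polish planned before the data were examined, and its alternative, the mean of log2 probe values, were not run. The table of values that the authors gave for the series held the same intensity, since 22464 of its 22464 values were equal to the feature averages with no tolerance. It was therefore an alternative without normalization.

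The array carried 1404 Ignicoccus genes, 177 segments between Ignicoccus genes, 1602 genes and 457 segments of another archaeon, Korarchaeum, and an average over 20000 random probes. No feature was named for N. equitans. Of the genes, 1292 had 120 probe spots. Gene names, products and positions on the chromosome came from the feature descriptions in the scanner files; the genome build and the strand were not given in the sources used here. A total of 543 genes had the product name hypothetical protein alone.

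Mean gene intensity per array ran from 6832 to 44391, and the median gene stood 22.4-fold to 181-fold above the random probes. All 1404 genes lay above the 95th percentile of the Korarchaeum genes on every array. Values of 60000 or more were treated as near the scanner ceiling. On both arrays of a group this held for 41 genes in pure culture at late log, 10 in co-culture at mid log, 4 in pure culture at early stationary and 1 in pure culture at late stationary phase. Co-culture replicate 1 alone had 137 such genes at late stationary and 35 at early stationary phase. Intensities are averages over spots, so that single spots can reach the ceiling in genes below that value. Where a gene near the ceiling on both arrays of a group compared is named, this is said. The number of arrays limits the precision.

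Background was corrected with normexp, fitted on all features with an offset of 50, and the log2 values of the 1404 genes were quantile normalized. Tests used limma 3.58.1 in R 4.3.3, with lmFit and eBayes without trend or robust options, and with 8 group means that shared 1 estimate of the spread per gene over all 16 arrays. Adjusted p-values are Benjamini-Hochberg values over all genes within each of 14 comparisons, and a gene is called below 0.05. Changes are log2 fold changes with the standard error (SE) from the fit, always co-culture minus pure culture or later minus earlier phase. Permutation tests and tables used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.

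Gene lists were written before the data were examined, as patterns on product names. They covered ribosomal proteins, aminoacyl-tRNA synthetases, translation factors, RNA polymerase, transcriptional regulators, RNA processing, DNA replication and repair, cell division, chaperones, proteases, protein secretion, pili and adhesion, glycosyltransferases, isoprenoid and membrane lipid synthesis, ABC transporters, other transporters, the ATP synthase, hydrogenases, sulfur and molybdopterin oxidoreductases, electron transfer proteins, the dicarboxylate/4-hydroxybutyrate cycle, gluconeogenesis, amino acid synthesis, purine and pyrimidine synthesis, cofactor synthesis, oxidative stress proteins, CRISPR-Cas and hypothetical proteins. Those 28 lists were tested by camera with an inter-gene correlation of 0.01, two-sided, adjusted over the lists within a comparison. Of the 32 lists, 4 were below the minimum of 3 members and were not tested: toxin-antitoxin proteins, transposases and metal homeostasis with 1 member each, and iron-sulfur cluster assembly with 2. Camera with an estimated correlation and fry were alternatives. Fry tests whether the genes of a list move one way on balance and does not compare them with other genes.

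Named genes followed a rule written before the data were examined. For the mean change in co-culture it took the 12 highest and 12 lowest called genes with an informative product name and 1 sign at all 4 phases, with the 3 highest and 3 lowest of the other genes. For each phase it took the 4 highest and 4 lowest called genes. For late stationary minus mid log it took the 10 highest and 10 lowest called genes with a product name in each culture. For the difference between the cultures in that change it took the 5 highest and 5 lowest, and for each step of the course the 2 highest and 2 lowest. In each list it took the 4 called members with the largest absolute change.

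Equal replicate numbers were checked for pairing. The deviations of same-numbered arrays from their group means correlated in all 28 pairs of groups, across genes, from 0.314 to 0.913 with a median of 0.790, so that the numbers pair the arrays. The pairing comes from the values, since the labels name no shared batch, and array serial series ran with the replicate number, so that a slide term equals the replicate block. The fit without the block was the main one, as fixed beforehand, and the fit with it an alternative.

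The procedure was tested on simulated data in 6 simulations with 200 of 1404 genes changed. For the mean change in co-culture the test alone recovered 88.7% of changes of 0.5 and 98.3% of changes of 1 on the log2 scale, and 4.17% of its calls were false. With background correction and quantile normalization included, 86.8% and 98.2% were recovered, 8.63% of calls were false, and a change of 1 was estimated at 0.92. At mid log alone these steps recovered 39.0% and 82.7%, with 4.67% of calls false. With the replicate block the shares of false calls were 16.2% for the mean change and 8.87% at mid log. The simulated noise was drawn separately for each array from the whole spread within groups, with a small replicate effect added. The pairing of same-numbered arrays was therefore weaker than in the data. These shares cannot say how many of the added calls with the block in the data are false. A list shifted by 0.4 was called by camera at an adjusted p of 2.485e-52, and 0 of the other lists were. Genes were simulated independently there and each member got the same shift, so that lists of correlated genes were not covered.

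The alternatives were no background correction, scaling to a common median, cyclic loess, all features in the normalization, the table of the series without normalization, the dimmest genes left out with 1053 kept, the replicate block, only the arrays compared, an intensity trend, an added limit on the fold change, and each array left out in turn. Chosen after seeing the data were the mean change without late stationary phase, genes near the ceiling left out, lists corrected by product name, synthetases without amidotransferase subunits, camera with an estimated correlation and the block, and the paired test of random probes and Korarchaeum features. The difference between the cultures in the last step was also added then.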

Results

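Transcript levels of 1404 Ignicoccus hospitalis genes were compared between cells grown alone and cells grown with Nanoarchaeum equitans. Each culture had 4 growth phases with 2 arrays per phase, 8 arrays per culture. Mean gene intensity ranged from 17983 to 33363 over the pure culture arrays and from 6832 to 44391 over the co-culture arrays, and both extremes were arrays of the late stationary co-culture. The first principal component held 34.7% of the variance.

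The mean difference over the 4 phases compared the host's transcripts with and without N. equitans, which depends on the host for metabolites. The labels do not say that the arrays of a culture came from separate runs. A difference between runs can therefore not be told apart from the presence of N. equitans. In co-culture, aminoacyl-tRNA synthetases and enzymes of the dicarboxylate/4-hydroxybutyrate cycle, the route of carbon dioxide fixation in this organism, were higher, as was a cluster of transporter genes. The call of the cycle ended with an estimated correlation (adjusted p = 0.510), and that of the synthetases with an estimated correlation and the replicate block (adjusted p = 0.0690). A short stretch with a tetrapyrrole methyltransferase and a prefoldin subunit held the strongest decrease. With n = 8 arrays per culture, limma called 809 genes, 436 higher and 373 lower, of which 44 changed by at least 1 on the log2 scale, 14 higher and 30 lower. With the replicate block the count was 1029, and in values without normalization it was 9.

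Among genes that were higher in co-culture, 4 neighbours from position 416932 to 420352 stood together. Igni_0470, an ABC transporter gene, was 2.76-fold higher (log2 change 1.47 ± 0.17, SE, adjusted p = 5.111e-05). Its neighbours Igni_0471 and Igni_0472, named as the periplasmic and permease components of a tungstate transporter, were 2.55-fold and 2.56-fold higher (log2 changes 1.35 ± 0.14 and 1.35 ± 0.05). Igni_0473, of unknown function, was 2.55-fold higher. Igni_0344, at positions 302251 to 302910, was 2.63-fold higher (1.39 ± 0.15, adjusted p = 1.974e-05). Its product name was phosphoenolpyruvate synthase, an enzyme that makes phosphoenolpyruvate from pyruvate. Whether this gene encodes the whole enzyme was not tested. The small subunit of carbamoyl-phosphate synthase, Igni_1400, which serves arginine and pyrimidine synthesis, was 2.33-fold higher (1.22 ± 0.04, adjusted p = 1.261e-08). The ferredoxin-like protein Igni_0173 and the alpha subunit of 2-oxoglutarate ferredoxin oxidoreductase Igni_1078 were each 2.03-fold higher, adenylosuccinate synthetase Igni_0346 2.02-fold and CTP synthetase Igni_0331 1.99-fold. Without late stationary phase the log2 change of Igni_1078 was 0.80 with an adjusted p of 0.0529. The transport permease Igni_1019, the LamG domain protein Igni_1030 and the phosphomethylpyrimidine kinase Igni_0888 rose between 1.97-fold and 1.99-fold. The signal of Igni_1019 was low, down to 2.67 times that of the random probes in pure culture and 3.25 times in co-culture. The hypothetical proteins Igni_1112 and Igni_1054 rose 2.29-fold and 2.20-fold.

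The strongest decrease was that of Igni_0089, a uroporphyrin-III C-methyltransferase gene at positions 85094 to 85840, 6.49-fold lower in co-culture (log2 change -2.70 ± 0.07, adjusted p = 2.296e-09). Such enzymes modify tetrapyrroles on the way to siroheme and cobalamin. Its lowest signal in co-culture was still 2.65 times that of the random probes. Next to it, the hypothetical gene Igni_0088 was 5.16-fold lower and Igni_0087, a prefoldin alpha subunit that passes unfolded proteins to chaperonins, was 4.24-fold lower (-2.08 ± 0.10). The ribosomal-protein-alanine acetyltransferase Igni_0578 was 3.15-fold lower (-1.65 ± 0.08). The adjacent genes Igni_0632, a GTP cyclohydrolase, and Igni_0633, a spermine synthase, were 2.66-fold and 2.46-fold lower. Decreases between 2.06-fold and 2.56-fold were found for the cupin protein Igni_0974, the auxin efflux carrier family member Igni_1095, the DEAD/DEAH helicase Igni_0145, the protein repair methyltransferase Igni_0877, the phosphate uptake regulator PhoU Igni_0607, the nascent polypeptide associated complex protein Igni_0603 and the Ser-tRNA(Thr) hydrolase Igni_0396. The hypothetical proteins Igni_0896 and Igni_1244 were 3.61-fold and 3.28-fold lower.

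**Figure D1:**
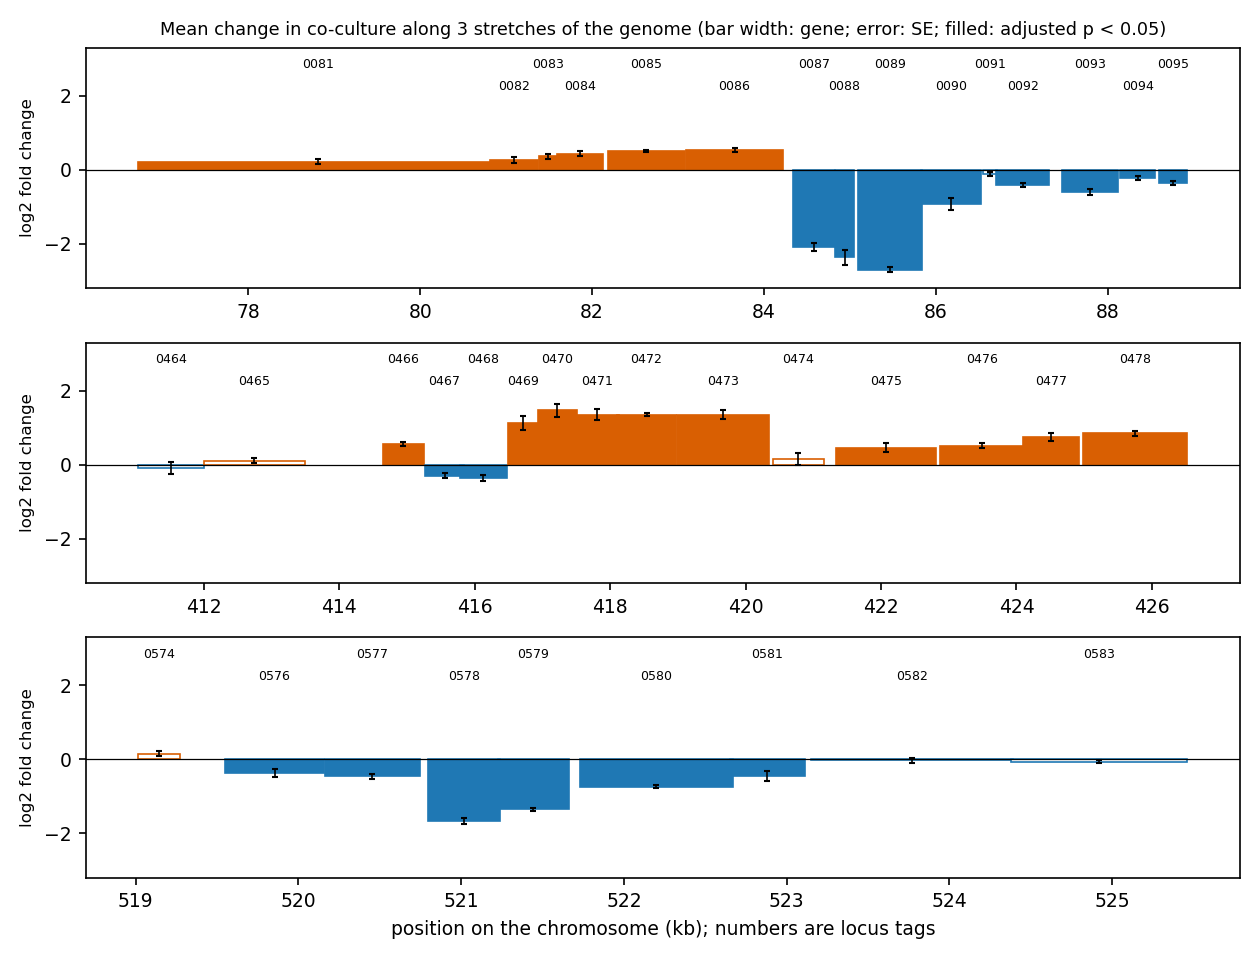
Mean log2 fold change in co-culture (vertical axis) against position on the chromosome in kb (horizontal axis) for 3 stretches; bars span genes, error bars are SE, and filled bars have an adjusted p below 0.05. The changes of Igni_0087, Igni_0088 and Igni_0089 were -2.08, -2.37 and -2.70, and those of Igni_0470 to Igni_0473 lay between 1.35 and 1.47.

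The list of aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, held 19 synthetase genes and 2 tRNA amidotransferase subunits. Of these 21 genes 16 were higher and 1 was lower in co-culture, 16 and 1 also when adjusted over the list alone, and of the 19 synthetase genes 15 and 1. The median change was 0.46, a factor of 1.38, and camera gave an adjusted p of 0.000674, with an adjusted p = 0.0469 with an estimated correlation. Without the amidotransferase subunits these were 0.000656 and 0.0488. The alpha subunit of phenylalanyl-tRNA synthetase Igni_1227 was 1.95-fold higher, tyrosyl-tRNA synthetase Igni_0347 1.59-fold and cysteinyl-tRNA synthetase Igni_0991 1.55-fold, and the tRNA amidotransferase gene Igni_0916 rose 1.82-fold. With the replicate block and an estimated correlation the adjusted p was 0.0690.

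In the dicarboxylate/4-hydroxybutyrate cycle 13 of 18 genes were higher and 0 were lower, or 14 adjusted over the list alone, with a median change of 0.38 and a camera adjusted p of 0.00104. The adjusted p was 0.510 with an estimated correlation. Beside Igni_0344, succinate dehydrogenase subunits C (Igni_0420) and A (Igni_0276) rose 1.73-fold and 1.70-fold. The alpha subunit of pyruvate ferredoxin oxidoreductase (Igni_1258) rose 1.61-fold. Of 65 ribosomal protein genes 31 were higher and 4 lower, with a median of 0.15 and an adjusted p of 0.00752, against an adjusted p = 0.569 with an estimated correlation; the median turned to -0.14 in values without normalization, where all genes shifted by -0.24. The S27E gene Igni_0103 went against the list, 1.95-fold lower; on both pure culture late log arrays it was near the scanner ceiling. Hypothetical proteins leaned down, with 130 of 546 higher, 183 lower, a median of -0.06 and an adjusted p of 0.0308, or an adjusted p = 0.510 with an estimated correlation. This call also ended without genes near the ceiling (0.0710) and without pure culture early stationary replicate 2 (0.0568), co-culture late log replicate 1 (0.0524) or co-culture late stationary replicate 2 (0.0592).

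The other lists did not pass the camera test for the mean change. Each had called members, but 57.6% of all 1404 genes were called, 436 higher and 373 lower. Called members alone therefore set no list apart. Isoprenoid and membrane lipid synthesis had 5 of 8 genes higher and 1 lower (adjusted p = 0.203). The archaeal lipid enzyme Igni_0416, a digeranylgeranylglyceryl phosphate synthase, rose 1.72-fold and isopentenyl pyrophosphate isomerase Igni_0804 rose 1.61-fold, while the polyprenyltransferase Igni_0457 fell 1.87-fold. ABC transporters had 8 of 22 higher and 2 lower (0.203), and amino acid synthesis 29 of 65 higher and 12 lower (0.203). Transcriptional regulators had 5 of 23 higher and 11 lower (0.203), and oxidative stress proteins 0 of 3 higher and 2 lower (0.203). Electron transfer proteins had 12 of 32 higher and 3 lower (0.214), and RNA polymerase with basal factors 6 of 15 higher and 0 lower (0.227). Chaperones had 2 of 10 higher and 5 lower (0.366), and cell division 0 of 3 higher and 2 lower (0.366). DNA replication and repair had 12 of 27 higher and 4 lower (0.438), with ATP-dependent DNA ligase Igni_1251 1.83-fold lower and endonuclease IV Igni_1092 1.57-fold higher. Cofactor synthesis had 10 of 46 higher and 15 lower (0.438).

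Gluconeogenesis had 5 of 12 higher and 2 lower, and protein secretion 4 of 12 higher and 2 lower (adjusted p = 0.486 for both). Translation factors had 2 of 14 higher and 5 lower, RNA processing 5 of 13 higher and 1 lower, hydrogenases 5 of 10 higher and 2 lower, and purine and pyrimidine synthesis 11 of 29 higher and 6 lower (0.609 for each). CRISPR-Cas, a defence system against foreign DNA, had 5 of 14 higher and 6 lower (0.647). The ATP synthase had 3 of 7 higher and 0 lower (0.731), and other transporters 4 of 16 higher and 5 lower (0.821). Pili and adhesion had 2 of 5 higher and 1 lower, glycosyltransferases 3 of 8 higher and 2 lower, and sulfur and molybdopterin oxidoreductases 2 of 11 higher and 2 lower (0.954 for each). Proteases had 5 of 23 higher and 4 lower (0.995). Estimated correlations called none of these lists.

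The change in co-culture at each phase asked when in growth the cultures parted. At mid log the synthetases stood out, with 18 of 21 genes higher, and Igni_0089 was 11.1-fold lower. At late log the tungstate transporter cluster led the increases and CRISPR-Cas genes were lower, a list call that ended with an estimated correlation (adjusted p = 0.467) and without the dimmest genes (adjusted p = 0.125). At early stationary phase no list passed the test. At late stationary phase the carbon fixation cycle did, though not with an estimated correlation (adjusted p = 0.599), and with the replicate block 3 lists passed. Limma called 595 genes at mid log, 437 at late log, 417 at early stationary and 603 at late stationary phase, with n = 2 arrays per group and the spread shared over 16 arrays. With the replicate block the late log count was 740 and the early stationary count 736. With median scaling the counts at late log, early and late stationary phase were 266, 153 and 274, with only the arrays compared 106 and 268 at the stationary phases, and without normalization 2 or fewer at each phase. Genes called in the same direction at all 4 phases numbered 47 higher and 40 lower, and 158 genes were called higher at one phase and lower at another.

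At mid log, 310 genes were higher and 285 lower. Carbamoyl-phosphate synthase Igni_1400 rose 3.53-fold (log2 change 1.82 ± 0.08, adjusted p = 3.613e-07), the riboflavin enzyme Igni_0421 3.51-fold, the hypothetical protein Igni_1298 3.31-fold and the aromatic amino acid enzyme Igni_1288 2.91-fold. Igni_0088 fell 12.1-fold (-3.59 ± 0.39), Igni_0089 11.1-fold (-3.47 ± 0.14), Igni_1244 7.56-fold and Igni_0087 7.54-fold. For the synthetases the median was 0.63 and the adjusted p 2.071e-05, with an adjusted p = 0.0172 with an estimated correlation. Cysteinyl-tRNA synthetase Igni_0991 rose 2.72-fold and methionyl-tRNA synthetase Igni_1155 2.27-fold. A further 6 lists passed camera, none of them with an estimated correlation. Ribosomal proteins had 21 of 65 higher and 2 lower (adjusted p = 0.00116, estimated correlation 0.441 as adjusted p). ABC transporters had 10 of 22 higher and 0 lower (0.0215, then 0.303). Amino acid synthesis had 27 of 65 higher and 7 lower (0.0190, then 0.303), and the carbon fixation cycle 7 of 18 higher and 0 lower (0.0287, then 0.441). Chaperones had 0 of 10 higher and 5 lower (0.0182, then 0.441), with Igni_0603 2.66-fold and the small heat shock protein Igni_1363 1.76-fold lower. The call of Igni_1363 ended with median scaling (adjusted p = 0.131) and without pure culture mid log replicate 2 (0.102) or co-culture mid log replicate 1 (0.140). Hypothetical proteins had a median of -0.06 (0.0247), which turned to 0.09 without normalization, where all genes shifted by 0.23. Leaving out pure culture mid log replicate 2 or co-culture mid log replicate 1 gave adjusted p-values of 0.0867 and 0.0545 for the carbon fixation cycle and 0.0788 and 0.0516 for hypothetical proteins.

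At late log, 226 genes were higher and 211 lower. The transporter genes Igni_0470, Igni_0471 and Igni_0472 rose 3.44-fold, 3.10-fold and 2.83-fold, and Igni_0344 rose 2.97-fold. Igni_0578 fell 9.02-fold (-3.17 ± 0.16, adjusted p = 5.374e-07) and its neighbour Igni_0579 6.63-fold, the hypothetical gene Igni_0101 8.54-fold and Igni_0089 5.35-fold. Synthetases had 11 of 21 higher and 1 lower, with a median of 0.60 and an adjusted p of 0.000353, or an adjusted p = 0.0382 with an estimated correlation and 0.0622 when the replicate block was added to it. Ribosomal proteins had 22 of 65 higher and 1 lower (0.000779) and the carbon fixation cycle 6 of 18 higher and 0 lower (0.00646); both medians turned negative in values without normalization, -0.11 and -0.16, where all genes shifted by -0.37. In CRISPR-Cas 7 of 14 genes were lower and 0 higher, with a median of -0.27 and an adjusted p of 0.00358. The Csa1 gene Igni_1132 fell 3.55-fold, Cas1 Igni_1133 3.07-fold and Cas4 Igni_1135 2.17-fold. For these last 3 lists the adjusted p was 0.467 with an estimated correlation. Without the dimmest genes the adjusted p of CRISPR-Cas was 0.125.

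At early stationary phase, 211 genes were higher and 206 lower. The radical SAM protein Igni_0332 rose 3.48-fold, the AsnC family regulator Igni_0308 3.23-fold, phenylalanyl-tRNA synthetase alpha Igni_1227 3.16-fold (1.66 ± 0.09, adjusted p = 2.969e-06) and Igni_0470 3.13-fold. The hypothetical gene Igni_0823 fell 18.5-fold (-4.21 ± 0.32, adjusted p = 1.804e-05), the BtpA family gene Igni_0822 7.47-fold, Igni_0089 4.37-fold and Igni_0330 4.12-fold. Synthetases had 3 of 21 genes higher and 2 lower (adjusted p = 0.704). The call of Igni_0470 ended with median scaling (1.47, adjusted p = 0.0794) and with only the arrays compared (1.65, adjusted p = 0.0652).

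At late stationary phase, 331 genes were higher and 272 lower. Ribonuclease H Igni_1153, which degrades RNA in RNA-DNA hybrids, rose 4.67-fold (2.22 ± 0.17, adjusted p = 1.365e-05), its neighbour Igni_1154 4.52-fold, Igni_0344 3.65-fold and Igni_0473 3.49-fold. Igni_0101 fell 14.5-fold (-3.86 ± 0.15), Igni_0823 7.68-fold, Igni_0089 6.86-fold and Igni_1314 5.75-fold. The carbon fixation cycle had 12 of 18 genes higher and 0 lower, with a median of 0.57 and an adjusted p of 0.00260, against an adjusted p = 0.599 with an estimated correlation. Its pyruvate ferredoxin oxidoreductase Igni_1258 rose 3.08-fold, and succinyl-CoA synthetase beta Igni_0086 and alpha Igni_0085 rose 2.08-fold and 1.80-fold. Across genes, which are not independent replicates, the changes in co-culture at different phases correlated from 0.272 (mid log with early stationary) to 0.651 (mid log with late log).

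**Figure D2:**
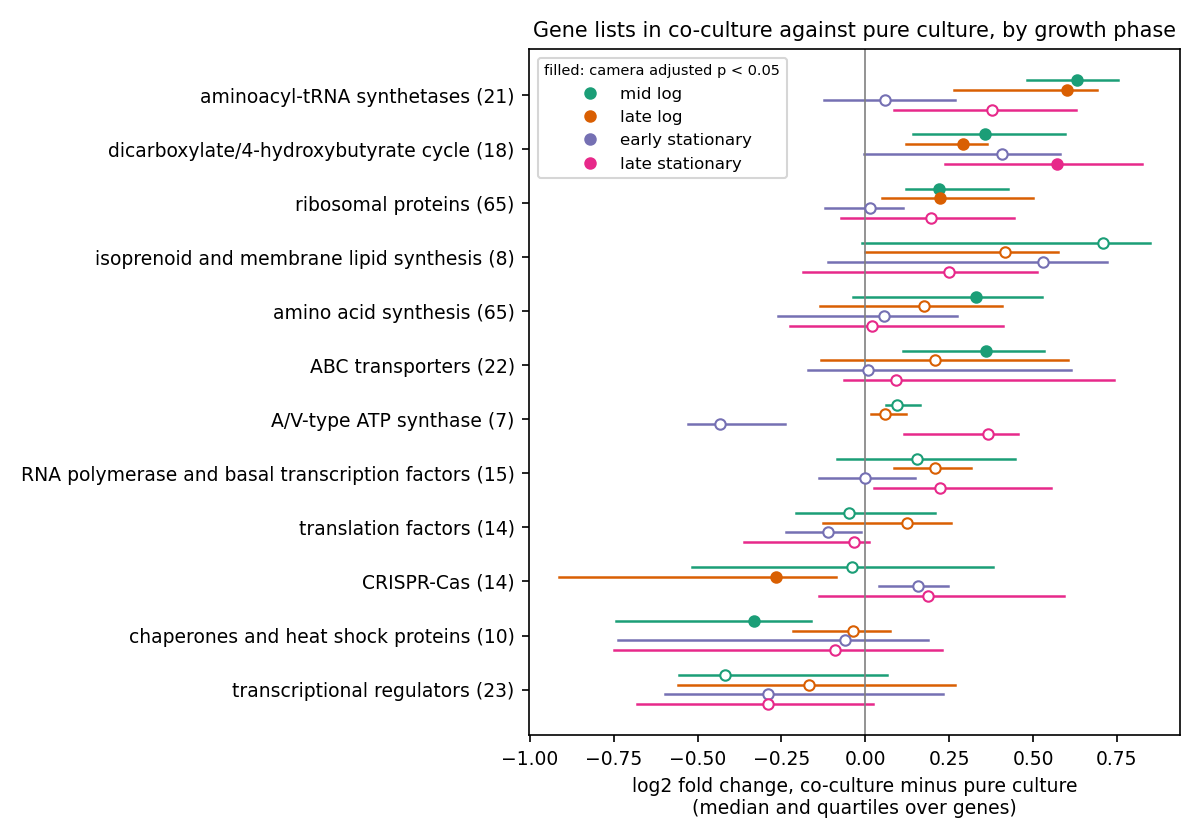
Median log2 fold change in co-culture (horizontal axis, bars span the quartiles over genes) for 12 gene lists at 4 growth phases, with the number of genes in parentheses and filled points where camera gave an adjusted p below 0.05. Synthetase medians were 0.63 and 0.60 at mid and late log, and the carbon fixation cycle reached 0.57 at late stationary phase; without normalization the late log medians of ribosomal proteins and of that cycle turned to -0.11 and -0.16.

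The change from mid log to late stationary phase described the growth course of each culture. In pure culture the ATP synthase and the carbon fixation cycle were lower in late stationary phase, list calls that ended with an estimated correlation (adjusted p = 0.224 and 0.811). Transcriptional regulators of the AsnC and TrmB families were among the strongest increases. In pure culture 576 genes were called, 277 higher and 299 lower, and 270 and 141 with median scaling; without normalization 0 were called in either course. The AsnC regulator Igni_0308 rose 4.82-fold (2.27 ± 0.31, adjusted p = 0.000257), the TrmB regulator Igni_1142 4.73-fold and the transporter Igni_1008 3.16-fold. Prephenate dehydratase Igni_0307 rose 3.07-fold and 6 further genes, Igni_0219, Igni_0103, Igni_0242, Igni_0550, Igni_0317 and the protease Igni_1005, rose between 2.44-fold and 2.95-fold. Ribonuclease H Igni_1153 fell 5.70-fold (-2.51 ± 0.17), adenylosuccinate synthetase Igni_0346 4.54-fold, prefoldin Igni_1176 4.35-fold and the putative transcription elongation factor Igni_0059 4.02-fold. Decreases between 2.96-fold and 3.71-fold were found for Igni_1175, Igni_1211, Igni_1256, Igni_1082, Igni_1200 and Igni_0457. The call of Igni_1200 ended with median scaling (-0.54, adjusted p = 0.423). Of 7 ATP synthase genes 6 were lower and 0 higher, with a median of -0.62 and an adjusted p of 0.00949, or an adjusted p = 0.224 with an estimated correlation. Subunit F Igni_1081 fell 2.93-fold and subunit I Igni_0609 2.07-fold. In the carbon fixation cycle 11 of 18 genes were lower and 1 higher, with a median of -0.43 and an adjusted p of 0.00761, or an adjusted p = 0.811 with an estimated correlation. Igni_1258 fell 2.83-fold and Igni_0086 2.32-fold, while Igni_0420 rose 2.10-fold. Without genes near the ceiling its adjusted p was 0.0556, and without the dimmest genes that of the ATP synthase was 0.0920.

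In co-culture 554 genes were called between mid log and late stationary phase, 280 higher and 274 lower, with 850 under the replicate block and 347 with only the arrays compared. Ribosomal proteins were the 1 list that passed, against 6 lists with the replicate block, with 21 of 65 genes lower and 1 higher, a median of -0.22 and an adjusted p of 0.00119, or an adjusted p = 0.566 with an estimated correlation. L40e Igni_0838 fell 2.98-fold and L34E Igni_1197 2.42-fold. The BtpA family gene Igni_0822 fell 4.88-fold (-2.29 ± 0.32, adjusted p = 0.000401), Igni_0059 3.40-fold and the diphthine synthase Igni_0657 2.95-fold. Igni_0853, Igni_0661, Igni_0346, Igni_0406, Igni_1288 and Igni_0399 fell between 2.59-fold and 2.90-fold. The riboflavin pathway enzyme Igni_0956 rose 2.96-fold (1.57 ± 0.28), the ferredoxin-like Igni_1238 2.73-fold, Igni_0219 2.49-fold and the polyprenyltransferase Igni_0457 2.43-fold. Igni_1331, Igni_0308, Igni_1142, the cytidylate kinase Igni_0756, the protease Igni_1005 and the sodium/hydrogen exchanger Igni_0394 rose between 2.20-fold and 2.39-fold. Calls of Igni_1238, Igni_0308 and Igni_0394 ended with only the arrays compared, at adjusted p-values of 0.103, 0.0618 and 0.0861, and without co-culture mid log replicate 1, at 0.0555, 0.0799 and 0.0530, where the log2 change of Igni_0308 was 0.75. Leaving out co-culture mid log replicate 2 ended those of Igni_1331, Igni_1142, Igni_0838, Igni_1238 and Igni_0394, at 0.0942, 0.0635, 0.0503, 0.174 and 0.141, and leaving out late stationary replicate 1 ended the same 5, at 0.0804, 0.0510, 0.0520, 0.242 and 0.195.

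The steps of the course showed where the cultures changed. From mid to late log, pure culture changed little, with 110 genes called, 62 higher and 48 lower, with 396 under the replicate block, 52 with median scaling, 33 with only the arrays compared and 32 to 40 with 1 array left out. Igni_0101 rose 4.63-fold and Igni_0578 3.97-fold, while Igni_1248, an isopropylmalate dehydratase subunit, fell 2.37-fold and prefoldin Igni_1176 2.32-fold. The carbon fixation cycle was lower as a list (median -0.28, adjusted p = 0.00172, and adjusted p = 0.655 with an estimated correlation), a median that turned to 0.08 without normalization, where all genes shifted by 0.34. The call of Igni_1248 ended with only the arrays compared (adjusted p = 0.0654) and without mid log replicate 2 (0.106) or late log replicate 1 or 2 (0.117 and 0.0520).

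In co-culture the same step called 309 genes, 155 higher and 154 lower, with 625 under the replicate block, 137 with only the arrays compared and 123 to 211 with 1 array left out. Igni_1244 rose 3.47-fold and Igni_0333 3.12-fold, and Igni_0823 and Igni_0661 fell 3.92-fold and 3.46-fold. Camera called lower levels of electron transfer proteins (median -0.34, adjusted p = 0.00667), the carbon fixation cycle (-0.26, 0.00667), CRISPR-Cas (-0.26, 0.00667), amino acid synthesis (-0.19, 0.00807), synthetases (-0.37, 0.0234) and gluconeogenesis (-0.26, 0.0400). Transcriptional regulators (0.30, 0.0400) and hypothetical proteins (0.09, 0.00606) were higher; the last median was -0.14 without normalization, where all genes shifted by -0.24. No list passed with an estimated correlation, where the adjusted p of the synthetases was 0.213. CRISPR-Cas also lost its call with median scaling (0.108) and cyclic loess (0.0561), synthetases without the dimmest genes (0.0870), and regulators and gluconeogenesis without the dimmest genes (0.0539 and 0.159) or genes near the ceiling (0.0859 and 0.0714). Gluconeogenesis lost it with an intensity trend (0.0519). Without co-culture late log replicate 2 the adjusted p-values were 0.0632 for synthetases, 0.289 for regulators, 0.110 for electron transfer and 0.225 for gluconeogenesis, and without co-culture mid log replicate 1 they were 0.154 for regulators and 0.0843 for gluconeogenesis.

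From late log to early stationary phase, 254 genes were called in pure culture, 136 higher and 118 lower, with 573 under the replicate block, 124 with median scaling (79 higher, 45 lower), 121 with only the arrays compared and 130 to 172 with 1 array left out. Igni_0823 rose 7.49-fold and Igni_0330 5.22-fold, while Igni_0101 fell 7.41-fold and the Csa1 gene Igni_1132 6.32-fold. Synthetases rose (median 0.29, adjusted p = 0.0445) and CRISPR-Cas fell (median -0.19, adjusted p = 0.0445), and with the replicate block both adjusted p-values were 0.0519. They were 0.336 and 0.740 with an estimated correlation, 0.117 for both with median scaling and 0.0805 for both with only the arrays compared. Without the dimmest genes they were 0.0523 and 0.342, without pure culture late log replicate 2 they were 0.0553 for both, and without early stationary replicate 1 they were 0.128 for both. For synthetases the value was 0.0658 without early stationary replicate 2, 0.112 without genes near the ceiling and 0.0811 with the list corrected by product name. In co-culture 164 genes were called, 86 higher and 78 lower, with 471 under the replicate block, 44 with median scaling (39 higher, 5 lower), 0 with only the arrays compared and 56 to 83 with 1 array left out. The methyltransferases Igni_1184 and Igni_1115 rose 2.24-fold and 2.22-fold, and Igni_0388, a carboxy-lyase, and Igni_1215 fell 2.38-fold and 2.36-fold. These 4 calls ended with only the arrays compared, at adjusted p-values of 0.165, 0.198, 0.165 and 0.165, and those of Igni_1184, Igni_0388 and Igni_1215 with median scaling, at 0.0794, 0.345 and 0.0737. Leaving out late log replicate 2 gave 0.120 for Igni_1184 and 0.0979 for Igni_1115, early stationary replicate 1 gave 0.0992 for Igni_1184, and late log replicate 1 and early stationary replicate 2 gave 0.123 and 0.149 for Igni_1115. Ribosomal proteins were lower (median -0.16, adjusted p = 0.00121, and adjusted p = 0.768 with an estimated correlation). That call also ended without co-culture late log replicate 2 (0.0839), without early stationary replicate 1 (0.0747) and with fry (0.0617).

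From early to late stationary phase the measured levels changed again in pure culture and hardly did in co-culture. Pure culture had 568 called genes, 261 higher and 307 lower, with 855 under the replicate block, 267 with median scaling and 319 with only the arrays compared. Igni_0101 rose 9.16-fold, the AsnC regulator Igni_0308 7.99-fold (adjusted p = 4.59e-05), while Igni_0330 fell 11.7-fold and the S-layer-like protein Igni_0480 4.35-fold. Of 7 ATP synthase genes 6 were lower, with a median of -0.75 and an adjusted p of 0.00786, or an adjusted p = 0.158 with an estimated correlation and 0.0797 without the dimmest genes. In co-culture limma called 0 genes, with 107 at an unadjusted p below 0.05 and 48 with the replicate block, 24 higher and 24 lower. The standard deviation of the log2 change over genes was 0.19 in co-culture and 0.61 in pure culture. Signal compression may contribute to the narrow spread, since late stationary co-culture replicate 1 had 137 genes near the ceiling. The difference between the cultures in this step passed the threshold for 329 genes.

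**Figure D3:**
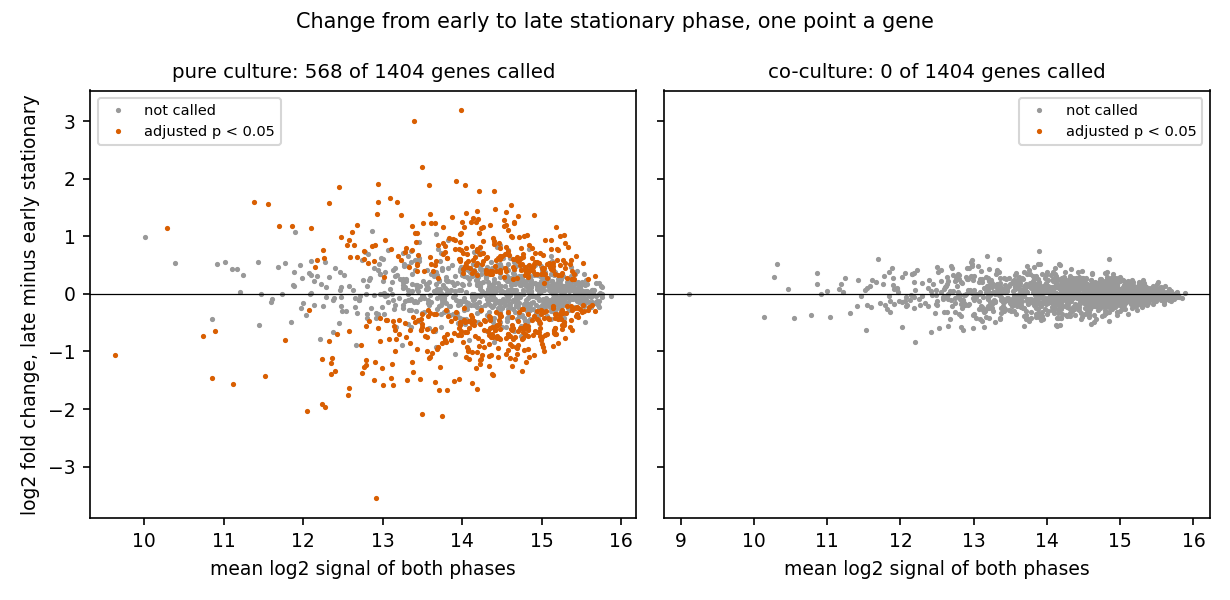
Log2 fold change from early to late stationary phase (vertical axis) against mean log2 signal (horizontal axis) for pure culture and co-culture, with 1 point per gene and called genes in colour. Pure culture had 568 called genes and a standard deviation of 0.61, co-culture 0 called genes and 0.19. Signal compression in co-culture may contribute.

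Whether the change from mid log to late stationary phase differed between the cultures was tested by the difference of the changes, co-culture minus pure culture. It was called for 357 genes, 189 higher and 168 lower, with 666 under the replicate block, 172 with median scaling and 236 without pure culture mid log replicate 2. No list passed camera. Igni_0101 differed most (-4.28 ± 0.22, adjusted p = 2.671e-06), followed by Igni_0823 (-3.45 ± 0.46), Igni_0105 (-2.80 ± 0.15), the nucleic acid binding protein Igni_0661 (-2.32 ± 0.23) and Igni_0827 (-2.32 ± 0.28). Higher in co-culture were the differences of Igni_0457 (2.85 ± 0.34, adjusted p = 0.000315), ribonuclease H Igni_1153 (2.63 ± 0.24), Igni_1154 (2.47 ± 0.39), Igni_1152 (2.24 ± 0.50) and Igni_0330 (2.12 ± 0.50). Igni_0457 fell 2.96-fold in pure culture and rose 2.43-fold in co-culture over the same interval. The call of Igni_1152 ended with median scaling (adjusted p = 0.0970), and that of Igni_0330 with only the arrays compared (adjusted p = 0.0575).

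**Figure D4:**
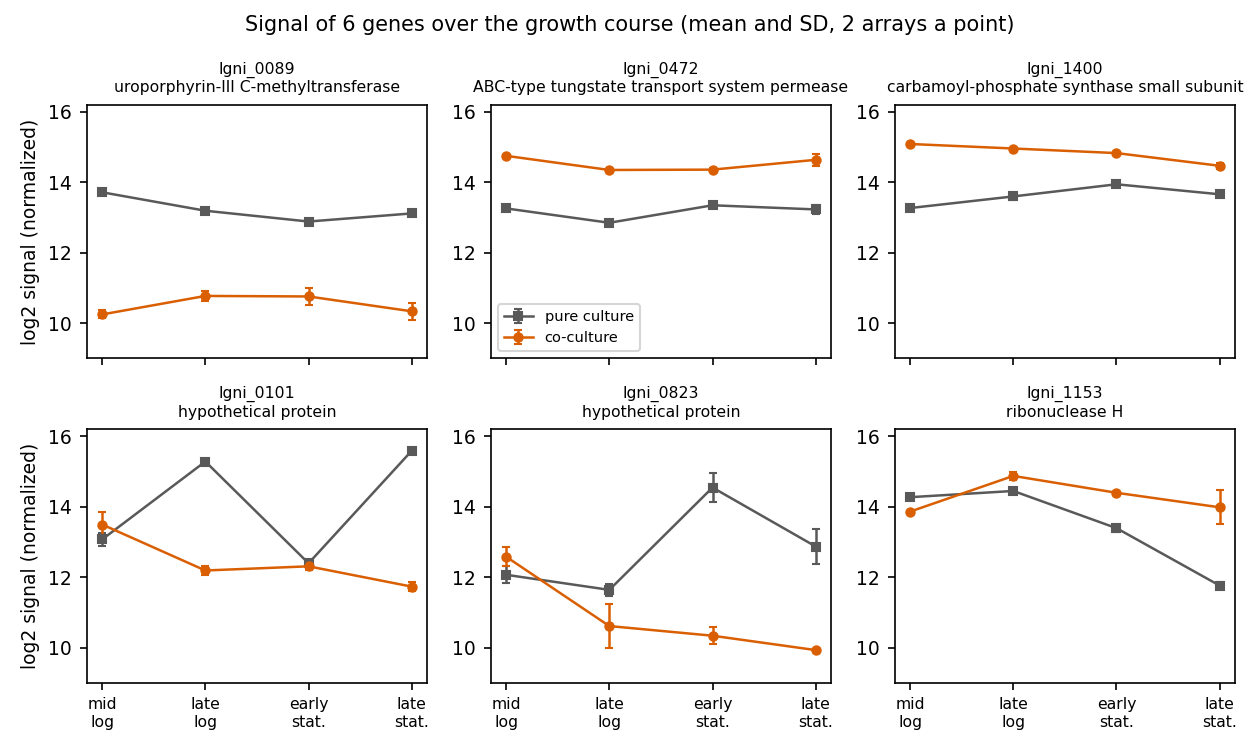
Normalized log2 signal (vertical axis, mean and SD of 2 arrays) over 4 growth phases (horizontal axis) for 6 genes in pure culture and co-culture. Igni_0089 lay lower and Igni_0472 and Igni_1400 lay higher in co-culture at every phase, while at late stationary phase Igni_0101 and Igni_0823 were 14.5-fold and 7.68-fold lower and Igni_1153 was 4.67-fold higher in co-culture.

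Random probes and Korarchaeum features, which are named for no Ignicoccus gene, showed no difference between the cultures that passed the threshold. Random probes were 0.07 higher in co-culture on the log2 scale (exact permutation test, two-sided, 8 against 8 arrays, p = 0.727), Korarchaeum genes 0.07 (p = 0.740) and Korarchaeum segments 0.06 (p = 0.761), with an adjusted p of 0.761 for each of the 3. With the arrays paired by phase and replicate number, an alternative chosen after seeing the data, co-culture was higher in 6 of 8 pairs for each. The exact p-values were then 0.109, 0.0469 and 0.0703, and the adjusted p-values 0.109, 0.105 and 0.105.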

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

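The test of signal compression in this part, and the difference between the cultures in the last step, were chosen after the result was seen. The growth courses of the cultures differed by a test of the difference itself: 357 genes were called for late stationary minus mid log and 329 genes, 186 higher and 143 lower, for late stationary minus early stationary phase.

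The single genes named here were called in the test of the difference from mid log to late stationary phase, co-culture minus pure culture. The polyprenyltransferase Igni_0457 differed by 2.85, ribonuclease H Igni_1153 by 2.63, its neighbours Igni_1154 and Igni_1152 by 2.47 and 2.24, and Igni_0330 by 2.12. Igni_0101 differed by -4.28, Igni_0823 by -3.45, Igni_0105 by -2.80, Igni_0661 by -2.32 and Igni_0827 by -2.32. In pure culture Igni_0101 rose, fell and rose again over the 3 steps (log2 changes 2.21, -2.89 and 3.20).

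From early to late stationary phase 0 genes were called in co-culture and 568 in pure culture, or 48 and 855 with the replicate block. The changes of both cultures correlated across genes at 0.0544. The fit shares 1 spread per gene, so that without the block the median SE was 0.151 in both. The lack of calls in that fit reflects smaller changes, with a spread over genes 0.321 times that of pure culture. Signal compression on the bright replicate 1 array, where 137 genes were near the ceiling, would leave replicate 2 with a spread like that of pure culture. The ratio was 0.517 within replicate 2 and lower, 0.359, within replicate 1, each from 1 array per group, so that compression may contribute. The replicate 2 arrays of the stationary co-culture were the dimmest, with the median gene 37.9-fold and 22.4-fold above the random probes. Whether low signal narrowed the spread within replicate 2 was not tested, so that replicate 2 is not a clean control. An earlier arrest of the co-culture, or samples taken closer together in time, may account for the pattern and was not tested.

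Features outside the gene comparisons also carried signal. Of the 177 segments between Ignicoccus genes, 175 lay above 95 percent of the Korarchaeum segments on all 16 arrays. The median segment per array ran from 3646 to 40049, against 5578.5 to 47349 for the median gene. The source of this signal between genes was not tested.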

How the results depend on the processing

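Directions were stable in the single genes reported and the lists called, except where named here or in the report. Without background correction all 14 counts stayed within a factor of 1.5, and so did those with all features in the normalization, with an intensity trend, without genes near the ceiling, and for the mean change without late stationary phase. The cause of each difference below was not tested unless fewer arrays or genes give it.

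Values without normalization gave 9 genes for the mean change (0 higher, 9 lower), 2 at mid log, 2 at late log, 1 at early and 0 at late stationary phase, and 0 for each step, each course and the difference of the courses; their medians shifted by up to -0.64. The 1 reversed gene was Igni_0276 in late log minus mid log of pure culture, at 0.077.

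An added limit of 1 on the absolute log2 change left 44 genes for the mean change, then 132, 88, 79 and 132 for the phases in order. It left 141 and 120 for late stationary minus mid log in pure culture and co-culture, 15 and 40 for late minus mid log, 49 and 12 for early stationary minus late log, 129 for the last step in pure culture and 127 for the difference of the courses.

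Median scaling gave 266 genes at late log, 153 at early and 274 at late stationary phase, 52 for late minus mid log and 124 for early stationary minus late log in pure culture, 44 for the latter in co-culture, 267 for the last step in pure culture and 172 for the difference of the courses. It raised the share of higher calls from 48.1% to 65.7% (270 higher, 141 lower) for late stationary minus mid log in pure culture, from 56.4% to 71.2% (37, 15) and from 53.5% to 63.7% (79, 45) for its first steps, and from 52.4% to 88.6% (39, 5) for early stationary minus late log in co-culture. It lowered that share at early stationary phase from 50.6% to 41.2% (63, 90) and at late stationary phase from 54.9% to 46.0% (126, 148). All features in the normalization lowered the share for late minus mid log in pure culture to 45.4% (44, 53). Cyclic loess gave 108 and leaving out the dimmest genes 109 for early stationary minus late log in co-culture.

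The replicate block, which pairs the arrays, gave 740 genes at late log, 736 at early stationary phase, 850 for late stationary minus mid log in co-culture, 396 and 625 for late minus mid log in pure culture and co-culture, 573 and 471 for early stationary minus late log, 855 and 48 for the last step, and 666 for the difference of the courses. All genes called without it were called with it in each comparison. It ended the 2 list calls of the step from late log to early stationary phase in pure culture and no other, and it added 10 list calls.

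Only the arrays compared, with fewer degrees of freedom and a spread from those arrays alone, gave 106 genes at early and 268 at late stationary phase, 347 for late stationary minus mid log in co-culture, 33 and 137 for late minus mid log in pure culture and co-culture, 121 and 0 for early stationary minus late log, and 319 for the last step in pure culture. Groups differed in spread. The SD over genes of the deviation from the group mean ran from 0.110 in co-culture at mid log to 0.190 at late stationary phase. It was 0.178 in co-culture at early stationary phase. The spread shared in the main fit may thus be too small for the stationary co-culture. The 2 reasons for lower counts were not told apart.

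With each array left out in turn, the lone array of its group was assumed to vary like the others. Counts ran from 745 to 823 for the mean change, 385 to 439 at mid log (385 without co-culture mid log replicate 1), 276 to 317 at late log (276 without pure culture late log replicate 1), 286 to 306 at early and 451 to 541 at late stationary phase. For late stationary minus mid log they ran from 371 to 428 in pure culture (371 without mid log replicate 1) and 338 to 518 in co-culture (350 and 338 without mid log replicates 1 and 2). For late minus mid log they ran from 32 to 40 in pure culture, under every array (40, 37, 32 and 38 without mid log replicates 1 and 2 and late log replicates 1 and 2), and 123 to 211 in co-culture (123, 145 and 155 without mid log replicates 1 and 2 and late log replicate 2). For early stationary minus late log they ran from 130 to 172 in pure culture (130, 132 and 162 without late log replicates 1 and 2 and early stationary replicate 1) and 56 to 83 in co-culture, under every array (83, 56, 59 and 76 in the same order). The last step gave 399 to 446 in pure culture and 0 to 12 in co-culture (12 without late stationary replicate 1), and the difference of the courses 236 to 395 (236 without pure culture mid log replicate 2).

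Of 392 list results 32 were calls, of which an estimated correlation ended 29 and left 3; fry, which compares no list with other genes, added 129. All genes exceeded the 95th percentile of the Korarchaeum genes, but on 4 arrays the dimmest gene lay below the highest of them. Leaving out the dimmest genes, with fewer tested, ended 8 list calls, so that a limit from low signal is not excluded. The ceiling limits the genes near it, and compression may reach further. On co-culture late stationary replicate 1 the median gene was at 47349. Its quartiles over genes lay 0.65 apart on the log2 scale, against 1.22 on replicate 2. Leaving out genes of 60000 or more does not test compression below that value. Background correction and normalization together, after simulated changes, raised the share of false calls in the mean change from 4.17% to 8.63%, and settings with more than 200 changed genes were not simulated.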

Other observations

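Tests of RNA from N. equitans and of growth stage in this part were chosen after the result was seen. The segments between genes changed in co-culture as well. In the mean over the 4 phases 94 of 177 segments were called, 24 higher and 70 lower. The segment next to Igni_0822, at positions 730956 to 731321 with 6 probe spots, was 3.43-fold lower (-1.78 ± 0.09, adjusted p = 1.903e-08). The next gene, Igni_0823, starts only at 734506. The segment between Igni_1112 and Igni_1113, with 2 probe spots, was 2.31-fold higher (1.21 ± 0.24). The largest decrease, 3.57-fold (-1.84 ± 0.20) at positions 1095657 to 1095869 with 4 probe spots, lay between genes that changed by 0.62 and -0.26. These segments were chosen after their values were seen. Across segments, which are not independent replicates, the change correlated with the mean change of the flanking genes (r = 0.534, rho = 0.522, permutation p = 1e-04, the smallest the permutations can give).

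Several genes not named so far were called in 1 direction at all 4 phases, and the ones named here were chosen after their values were seen. The tRNA-guanine transglycosylase Igni_0478, which serves archaeosine synthesis, and the diphthamide synthesis gene Igni_0998, which serves the modification of elongation factor 2, were higher at every phase by at least 0.75 and 0.70 on the log2 scale. The membrane transport genes Igni_1084 and Igni_1085 and their neighbour Igni_1083 were higher by at least 0.54, 0.68 and 0.64.

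The higher level of the synthetases in co-culture was weighed against 3 explanations. RNA of N. equitans hybridising to conserved genes is left open: translation factors, which both organisms carry, lay below the synthetases (difference of the medians -0.48, one-sided permutation p = 0.00033), but ribosomal proteins, which both carry too, were higher at a median of 0.15, percentile 99.9 of lists matched on signal, or -0.14 without normalization, where all genes shifted by -0.24. A bias with signal level would give the same median in lists matched on signal, and the synthetases stood at percentile 100 of 10000 such lists. A shift within the sampled growth course of the pure culture, from mid log to late stationary phase, would keep the list within its levels there. At mid log, where the list changed most, co-culture exceeded the highest pure culture phase by 0.51 ± 0.02 (SE). Pure culture was not sampled before mid log, so that an earlier growth stage of the co-culture is left open. Sequence similarity was not used here, RNA of N. equitans and a response of the host may both contribute, and with the replicate block and an estimated correlation the adjusted p was 0.0690.

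Neighbouring genes changed together in co-culture: the mean changes of 1400 adjacent pairs correlated at 0.503 (permutation p = 1e-04, the smallest the permutations can give), which was noticed in the strongest genes before it was tested. Shared transcription units are a candidate explanation. Pairs under 50 bases apart correlated at 0.582 and pairs over 200 bases apart at -0.014, a difference of 0.596 (one-sided permutation p = 1e-04, the smallest the permutations can give). Probes shared by overlapping genes would confine the correlation to overlapping pairs, and the 970 pairs that did not overlap kept 0.616 of it (0.420 against 0.682). Strand was not used, so that adjacent genes on opposite strands stay among the pairs.

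Chance in the assignment of arrays to cultures was tested on the mean change. Of 100 splits of the arrays within phases, out of 648 possible, 1 called as many genes as the real split, which was the real split itself with 809. The highest of the others called 599 and kept the true cultures at 3 of 4 phases. The count thus followed the true labels of these arrays. Any other split mixes or swaps the cultures at some phase. Fewer calls were therefore expected from it wherever the 2 arrays of a group are alike. Chance differences between cultures were not tested by these splits, since the 2 arrays of a group need not come from separate cultures. The split by replicate number called 14, and of the 21 splits that, like the real one, parted every same-numbered pair, the highest other called 388.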
